A study of Mus musculus with 12 samples.

How the data were processed

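RNA from 12 mouse tumours, 4 of each of 3 genotypes, was extracted with the miRNeasy mini kit and sequenced. The labels give the molecule as polyA RNA, while the library kit they name is the Illumina TruSeq Stranded Total RNA kit, so the selection of RNA is not settled by the labels. The authors' notes name bcl2fastq, Trimmomatic, STAR, featureCounts and DESeq2 without versions, and the mouse genome build mm10 (GRCm38). The strand setting of the counting was not given.

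The deposited raw table holds counts per gene symbol, made by the authors with no normalization. The deposited normalized table holds a signal that is the raw count divided by 1 size factor per library, as set by the authors. The deposited TPM table holds TPM values, made by the authors by dividing counts by gene length and scaling each library to the same sum. The 3 tables have 55341 gene symbols and 15 columns each, of which 12 were used and 3, which no sample label describes, were left out of every step. Checked on the values, 100% of the normalized values gave back the raw count within a tolerance of 0.02 reads. All 55341 symbols were found in GENCODE mouse release 21, which gave coordinates on GRCm38. Of these symbols, 108 have more than 1 gene identifier. They were given the coordinates of the identifier listed earliest and were left out of the runs of neighbouring genes.

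Total counts per library ran from 21515649 to 34430620, and 23433 to 25497 genes had at least 1 count. Group means were 24.5 ± 1.83 (SD, in 10 to the power of 6 counts) in Tp53-Ccne1-Akt2-Kras, 27.4 ± 5.15 in Tp53-Pten-Nf1 and 26.9 ± 4.48 in Tp53-Brca1-Myc, so the highest and lowest means differed by more than the SD within Tp53-Ccne1-Akt2-Kras and by less than the SD within each of the others. Between replicates the lowest chi-square per gene was 29.7, so on average over genes the spread between tumours exceeded counting error.

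Raw counts were normalized by TMM and tested with edgeR 4.0.16 (R 4.3.3) by a quasi-likelihood fit of all 12 libraries with 1 coefficient per genotype and 9 residual degrees of freedom. The filter filterByExpr (minimum count 10, minimum total 15) kept 17431 genes and left 37910 untested. The common biological coefficient of variation was 0.453. Each pair of genotypes was compared, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. An F-test asked which genes differed among the 3 genotypes. A genotype was counted as apart for a gene called in the same direction against both others. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM values were computed with TMM-scaled library sizes, and log2 CPM for scores and distances with a prior count of 2.

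Before the data were examined, 43 gene lists of pathways, cell types and signs of sample quality were fixed, of which 42 were tested with limma 3.58.1's camera at a preset correlation of 0.01, needing at least 3 tested genes. The comparisons, the alternatives and the rule for naming genes were also fixed then. That rule names the 8 engineered genes, the 10 higher and 10 lower genes of largest change per comparison (called, average log2 CPM of at least 2, no overlap between genotypes, no predicted gene, pseudogene, receptor segment or small RNA), up to 4 members of lowest p of each list described, and 8 genes per direction of largest smaller change for each genotype-apart set. The genes of the Hox clusters, the members of the runs of neighbouring genes and further host tissue genes were chosen after their values were seen.

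A list score is the mean log2 CPM of its tested members in a library, and scores were compared by exact permutation tests (two-sided, 4 against 4 or 4 against 8). Genotype separation was the mean distance between minus within genotypes, over the 1000 most variable genes, with an exact one-sided test over all 5775 partitions of the 12 tumours into 3 groups of 4. Chromosome values used 9454 protein-coding genes with an average log2 CPM of at least 4. Between genotypes they are the median log2 fold change of a chromosome's genes minus the median of all genes, set against 1000 relabellings of the genes. Per tumour they are the median of log2 CPM minus the gene's mean over the 12 tumours, centred on the library's median. Folds against a group with 0 counts use a floor of 3 counts over the 4 libraries, and ratios against 1 to 3 counts carry a 95% exact interval from the pooled counts.

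The alternatives tried were relative log expression and upper-quartile factors, no filter on low counts, a filter of CPM of at least 1 in at least 4 samples, limma-voom, limma-trend on TPM + 1 and TPM + 0.1, DESeq2 1.42.0, a fit of only the 2 genotypes compared, an absolute log2 fold change of at least 1, camera with an estimated correlation, fry, and each tumour left out in turn. The authors' size factors, leaving out Tp53-Ccne1-Akt2-Kras tumour 1 together with Tp53-Pten-Nf1 tumour 8, and exact permutation of list scores were added after seeing the data. The procedure was tested on simulated data with 100 genes changed by a fold of 2 and 100 by a fold of 4 among 17431. It recovered 11, 16 and 20 of the former and 75, 76 and 77 of the latter in the 3 comparisons, with 3.33, 5.94 and 3.96% false calls. The genes changed in this way were drawn from those with a mean CPM of at least 4. The macrophage and monocyte list was also raised by a fold of 2. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.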

Results

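RNA sequencing measured gene expression in 12 mouse tumours that had grown from genetically engineered organoids, which are epithelial cultures kept in a matrix and were here injected orthotopically as an ovarian cancer model. Tumours were taken 2 months after injection. By their labels, all 3 genotypes lacked Tp53 (mouse symbol Trp53), which encodes the stress-response transcription factor p53. The Tp53-Ccne1-Akt2-Kras tumours (below, Ccne1/Akt2/Kras, tumours 1 to 4) were labelled as overexpressing cyclin E1, the kinase AKT2 and the GTPase KRAS. The Tp53-Pten-Nf1 tumours (Pten/Nf1, tumours 5 to 8) were labelled as also lacking Pten, a brake on PI3K signalling, and Nf1, a brake on RAS. The Tp53-Brca1-Myc tumours (Brca1/Myc, tumours 9 to 12) were labelled as also lacking the DNA repair gene Brca1 and overexpressing the transcription factor Myc. The labels describe the 4 tumours of each genotype as independent, but do not say whether they grew from separate organoid clones, so a difference between genotypes is not shown to be an effect of the engineered genes; the series holds no normal tissue or parental organoids among the samples compared. Ccne1/Akt2/Kras tumours 1, 2, 3 and 4 had 23249050, 25690152, 22662044 and 26422803 counts. Pten/Nf1 tumours 5, 6, 7 and 8 had 23291844, 23844175, 28198784 and 34430620 counts. Brca1/Myc tumours 9, 10, 11 and 12 had 27364993, 21515649, 32434193 and 26318536 counts. Counting intervals and floors given below use counts pooled over the 4 tumours of a genotype, so they leave out the spread between tumours. They cover counting error only, and the reads carry no molecular identifiers.

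The tumours grouped by genotype, and the Ccne1/Akt2/Kras tumours stood farthest from the rest. Over the 1000 most variable genes, the nearest other tumour had the same genotype for 12 of 12 tumours. The mean distance between tumours was 106 within Ccne1/Akt2/Kras, 67.5 within Pten/Nf1 and 59.3 within Brca1/Myc (Euclidean, on log2 CPM, counts scaled for library size). Between genotypes it was 139 for Ccne1/Akt2/Kras and Pten/Nf1, 141 for Ccne1/Akt2/Kras and Brca1/Myc, and 90.2 for Pten/Nf1 and Brca1/Myc. The mean distance between genotypes exceeded that within by 45.7, with an exact permutation p of 0.000173 (one-sided, 5775 partitions), the smallest these permutations can give. Ccne1/Akt2/Kras tumour 1 lay apart from its group, at a mean distance of 121 from the other tumours of its genotype. Across the 3 genotypes, 6518 of 17431 tested genes (37.4%) differed by the edgeR F-test at an adjusted p under 0.05.

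**Figure D1:**
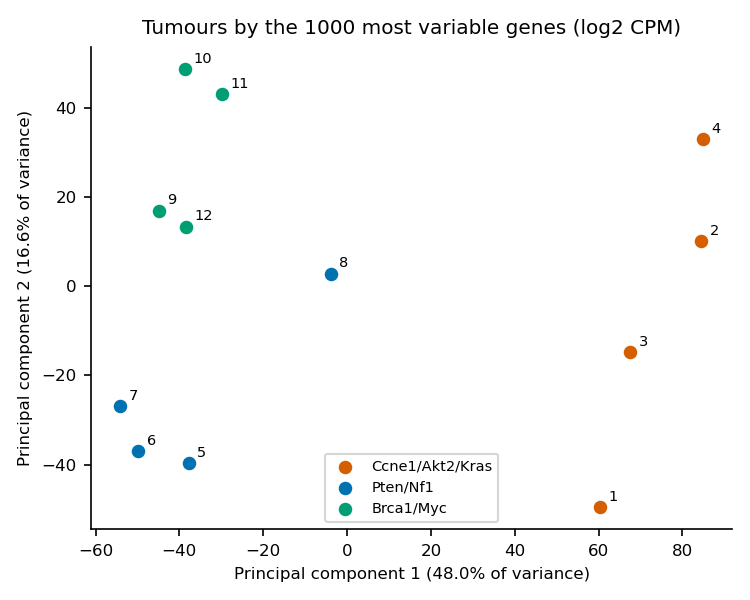
Principal components 1 and 2 (48.0% and 16.6% of the variance) of log2 CPM over the 1000 most variable genes. Each point is a tumour, numbered 1 to 12 and coloured by genotype; the 4 Ccne1/Akt2/Kras tumours lie apart from the 8 others along component 1.

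Of the genes labelled as overexpressed, Ccne1, Akt2 and Myc were higher in gene counts in the tumours with that label, and Kras was lower. An introduced copy from another species or with altered codons can be missed by alignment, so these counts neither prove nor disprove a label. Ccne1 (ENSMUSG00000002068.16, chromosome 7, 38097984 to 38107534) had a mean of 23.2 ± 13.9 CPM (SD, n = 4) in Ccne1/Akt2/Kras tumours, 8.38 ± 2.56 in Pten/Nf1 and 7.57 ± 1.67 in Brca1/Myc. Akt2 (ENSMUSG00000004056.15, chromosome 7, 27591552 to 27640826) had 309 ± 123, 164 ± 32.5 and 143 ± 15.5 CPM in the same order. Ccne1 rose by a log2 fold change of 1.47 ± 0.39 (SE) over Pten/Nf1 and 1.61 ± 0.39 over Brca1/Myc (edgeR adjusted p = 0.0213 and 0.0096), and Akt2 by 0.91 ± 0.27 and 1.11 ± 0.27 (0.0339 and 0.00998). Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374) had 365 ± 25.9 CPM in Brca1/Myc, 126 ± 106 in Ccne1/Akt2/Kras and 77.4 ± 26.5 in Pten/Nf1, a log2 fold change of -1.54 ± 0.46 for Ccne1/Akt2/Kras and -2.24 ± 0.47 for Pten/Nf1 against Brca1/Myc (edgeR adjusted p = 0.0244 and 0.017). Kras (ENSMUSG00000030265.14, chromosome 6, 145216699 to 145250239) was lowest in the Ccne1/Akt2/Kras tumours at 54.5 ± 31.3 CPM, against 90.2 ± 12.03 in Pten/Nf1 and 125 ± 15.5 in Brca1/Myc. Its log2 fold change was -1.20 ± 0.30 against Brca1/Myc (edgeR adjusted p = 0.0118) and -0.73 ± 0.30 against Pten/Nf1 (0.107).

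The edgeR fit of all 12 libraries did not call Pten, Nf1 or Brca1 lower in the tumours labelled as lacking it, but fits without tumour 1 called Pten and Brca1 lower against Ccne1/Akt2/Kras. In the fit of all 12, Brca1 was lower in Brca1/Myc than in Ccne1/Akt2/Kras at an unadjusted p of 0.0352 (adjusted 0.0871, and 0.0661 with DESeq2). Pten had 88.8 ± 18.0 CPM in Pten/Nf1 tumours (SD, n = 4), against 107 ± 37.7 in Ccne1/Akt2/Kras and 78.0 ± 6.53 in Brca1/Myc. Nf1 had 110 ± 17.6 CPM in Pten/Nf1, between 81.0 ± 21.9 in Ccne1/Akt2/Kras and 142 ± 17.1 in Brca1/Myc, and fell by 0.81 ± 0.20 (log2, SE) in Ccne1/Akt2/Kras against Brca1/Myc (edgeR adjusted p = 0.0112). Brca1 had 20.6 ± 0.973 CPM in Brca1/Myc, 21.3 ± 7.26 in Pten/Nf1 and 31.5 ± 7.71 in Ccne1/Akt2/Kras. Trp53 had 28.6 ± 5.77, 23.3 ± 4.40 and 31.2 ± 4.28 CPM in Ccne1/Akt2/Kras, Pten/Nf1 and Brca1/Myc, and in the 3 comparisons its adjusted p was 0.311, 0.658 and 0.182, but limma-trend called it lower in Pten/Nf1 than in Brca1/Myc (adjusted p = 0.0214 on TPM + 1 and 0.0225 on TPM + 0.1). Gene-level counts do not show whether a transcript carries a disrupting edit. Ccne1/Akt2/Kras tumour 1 had 153 CPM of Akt2 against 295 to 450 in tumours 2 to 4, 101 CPM of Kras against 31.5 to 44.2, and 281 CPM of Myc against 53.7 to 105.

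Single libraries decided several of these calls. For Ccne1 against Pten/Nf1 the adjusted p was 0.0567 without tumour 5 and 0.0636 without tumour 7. For Akt2 against Pten/Nf1 it was 0.0596, 0.0565, 0.082, 0.0913, 0.062 and 0.0817 without tumours 2, 3, 4, 5, 7 and 8. For Myc in Ccne1/Akt2/Kras against Brca1/Myc it was 0.054, 0.0508, 0.0622 and 0.0569 without tumours 9, 10, 2 and 3, and in Pten/Nf1 against Brca1/Myc it was 0.0547, 0.0526 and 0.0557 without tumours 9, 10 and 5. Without tumour 1, Kras fell against Pten/Nf1 by 1.21 (log2, edgeR adjusted p = 0.000658) and Kras also passed in Pten/Nf1 against Brca1/Myc (0.0444). Without tumour 1, Pten rose in Ccne1/Akt2/Kras by 0.50 over Pten/Nf1 (0.0291) and 0.69 over Brca1/Myc (0.00511), and Brca1 rose by 0.76 over Brca1/Myc (0.031). With limma-trend on TPM + 1 the adjusted p of Akt2 was 0.0752 against Pten/Nf1 and 0.0727 against Brca1/Myc, within ranges over all its alternatives of 0.00183 to 0.0922 and 0.000556 to 0.073.

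**Figure D2:**
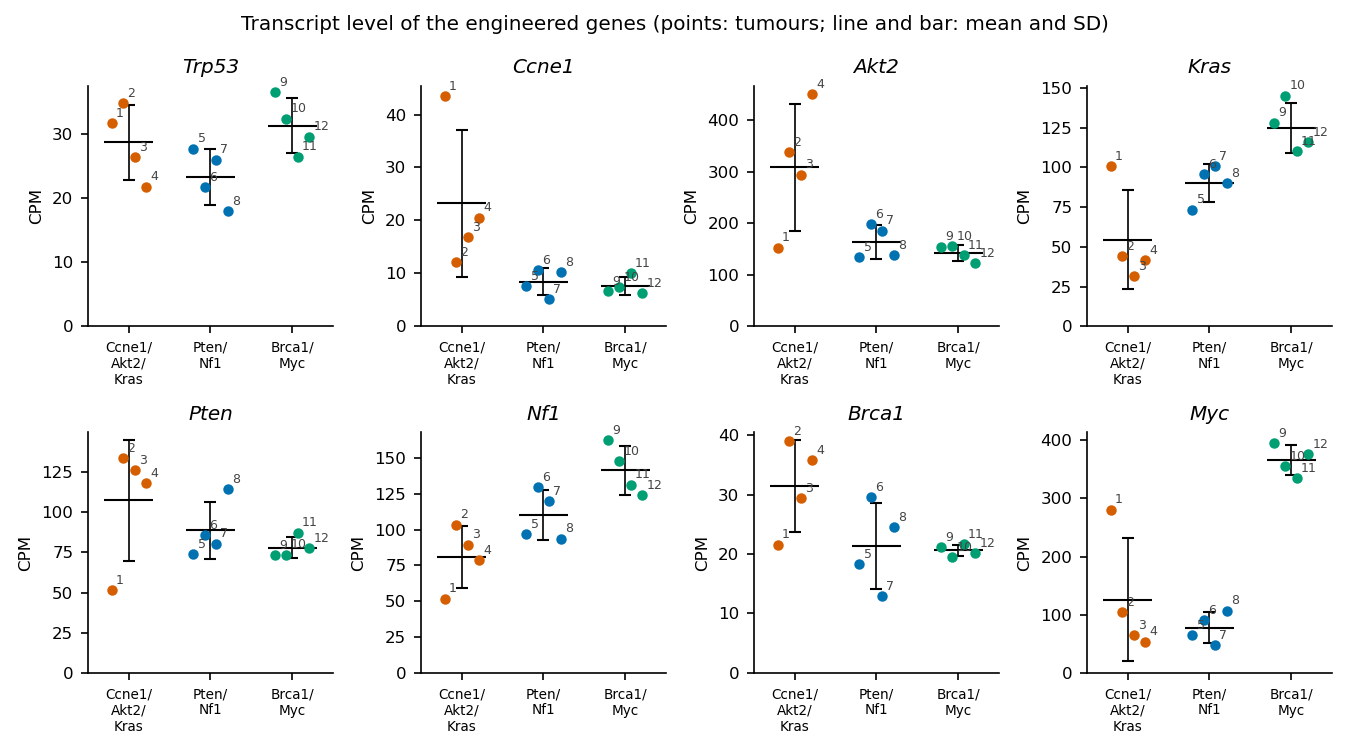
Transcript level in CPM of the 8 engineered genes in each tumour, by genotype; points are tumours with their numbers, and lines and bars are the mean and SD of 4. Akt2 was 295 to 450 CPM in Ccne1/Akt2/Kras tumours 2 to 4 and 153 in tumour 1.

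Ccne1/Akt2/Kras against Pten/Nf1 compares tumours labelled by oncogenes with tumours labelled by the loss of PI3K and RAS brakes. The gene counts of Kras, Pten and Nf1 did not follow these labels in the fit of all 12, which does not disprove the labels. Of the genes of the mesothelium, the cell layer that lines body cavities, 8 of 9 were lower in the Ccne1/Akt2/Kras tumours, as were 6 of 11 B and plasma cell genes and 6 of 12 mast cell and eosinophil genes. In the other direction, 9 of 32 cell cycle genes (1 fell) and 6 of 29 genes of homologous recombination and replication stress were higher. Each of these lists passed camera with a preset correlation and was lost with an estimated correlation (adjusted p = 0.947). Upk1b, a uroplakin made by mesothelium (ENSMUSG00000049436.5, chromosome 16, 38773184 to 38800328), had 5.96 ± 2.92 CPM (SD, n = 4) in Ccne1/Akt2/Kras and 335 ± 228 in Pten/Nf1. Brinp3 (ENSMUSG00000035131.14, chromosome 1, 146494760 to 146902472) had 63.7 ± 51.5 CPM in Ccne1/Akt2/Kras and 3 counts in all Pten/Nf1 libraries, a ratio of 2343 (95% counting interval 801 to 11366). Krt9, a keratin, had 0 counts in Ccne1/Akt2/Kras and 12.7 ± 4.09 CPM in Pten/Nf1, at least 426-fold lower against a floor of 3 counts over the group.

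In the mesothelium list, 8 of 9 tested members fell, 0 rose and 1 did not pass, with a median log2 fold change of -4.80. Upk1b fell by 5.81 ± 0.58 (log2, SE), Gpm6a fell by 5.91 ± 0.88, Lrrn4 fell by 4.80 ± 0.75 and the Wnt agonist Rspo1 fell by 4.83 ± 0.78. Adjusted over the list alone, 8 fell and 1 rose; the camera adjusted p was 5.06e-09, and adjusted p = 0.947 with an estimated correlation. Of 11 B and plasma cell genes, 6 fell, 0 rose and 5 did not pass (7 fell adjusted over the list alone, median -2.59), with a camera adjusted p of 0.00522 and adjusted p = 0.947 with an estimated correlation. The immunoglobulin genes Ighm, Igkc and Jchain had log2 fold changes of -2.73 ± 0.63, -5.96 ± 1.36 and -5.85 ± 1.28. Pten/Nf1 tumour 8 had 45.1 CPM of Jchain against 879 to 909 in tumours 5 to 7. Of 12 mast cell and eosinophil genes, 6 fell, 0 rose and 6 did not pass (8 fell adjusted over the list alone, median -2.80), with a camera adjusted p of 0.00138 and adjusted p = 0.947 with an estimated correlation. Prg2, the eosinophil major basic protein, fell by 5.14 ± 1.0, and the chymase Cma1 fell by 3.01 ± 0.80, with an adjusted p of 0.0516 without tumour 3.

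Among 32 tested cell cycle genes, 9 rose, 1 fell and 22 did not pass (15 rose and 1 fell adjusted over the list alone, median 0.75), with a camera adjusted p of 4.92e-05 and adjusted p = 0.947 with an estimated correlation. The replication factors Mcm5 and Gins2 and the cell cycle regulator Mybl2 rose by 1.49 ± 0.25, 1.06 ± 0.24 and 1.13 ± 0.26 (log2, SE), and Rrm1, a subunit of ribonucleotide reductase, fell by 0.90 ± 0.18. Among 29 genes of homologous recombination and replication stress, 6 rose, 0 fell and 23 did not pass (8 rose adjusted over the list alone, median 0.69), with a camera adjusted p of 0.000958 and adjusted p = 0.947 with an estimated correlation. Brca2, which loads RAD51 at breaks, rose by 1.31 ± 0.21. Among 32 interferon-stimulated genes, 6 rose, 0 fell and 26 did not pass (11 rose adjusted over the list alone, median 1.17), with a camera adjusted p of 0.000958 and adjusted p = 0.947 with an estimated correlation. The antiviral gene Oasl1 rose by 1.23 ± 0.29, and Ifi44 by 2.57 ± 0.65, with an adjusted p of 0.0508 without tumour 5 and 0.0542 without tumour 7. The mean log2 CPM of the interferon list was 4.44 and 5.33 in tumours 1 and 2, within the 4.39 to 5.35 of Pten/Nf1, and 6.53 and 6.80 in tumours 3 and 4 (exact permutation p = 0.229). The scores of both genotypes overlapped for 5 of the 8 lists called by camera here, which were those of B and plasma cells, the cell cycle, interferon, hypoxia and immediate early genes.

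Among 19 hypoxia and glycolysis genes, 4 fell, 0 rose and 15 did not pass (6 fell adjusted over the list alone, median -0.24), with a camera adjusted p of 0.0459 and adjusted p = 0.947 with an estimated correlation. Bnip3, a hypoxia-induced mitophagy receptor, fell by 1.01 ± 0.19 (log2, SE) and the kinase Pdk1 fell by 1.05 ± 0.23. The hypoxia list's adjusted p was 0.059, 0.233, 0.0882 and 0.0757 without tumours 2, 4, 6 and 8, in a range of 0.00065 to 0.947 over its alternatives. Of 17 immediate early and dissociation stress genes, 1 rose, 1 fell and 15 did not pass (0 in either direction adjusted over the list alone, where 8 rose and 1 fell at an unadjusted p under 0.05 in edgeR and 5 rose and 1 fell in DESeq2, median 0.59), with a camera adjusted p of 0.0459 and adjusted p = 0.947 with an estimated correlation. That list's adjusted p was 0.103, 0.069, 0.0906 and 0.0931 without tumours 1, 4, 5 and 7, in a range of 0.0095 to 0.947.

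The Müllerian and fallopian tube epithelium list did not pass (camera adjusted p = 0.126, adjusted p = 0.95 with an estimated correlation), although 10 of its 25 members rose, 2 fell and 13 did not pass (12 and 2 adjusted over the list alone, median 1.80). Its mean log2 CPM was 6.53 in tumour 1, 1.44 in tumour 2, and 3.80 and 4.44 in tumours 3 and 4, against 2.34 to 4.18 in Pten/Nf1. Grhl2, an epithelial transcription factor, rose by 7.49 ± 1.38 (log2, SE). Muc16, the CA125 antigen, and Wt1, both also made by mesothelium, had log2 fold changes of -6.41 ± 1.15 and -4.37 ± 0.84. Of 23 RAS-MAPK output genes, 6 rose, 3 fell and 14 did not pass (7 and 3 adjusted over the list alone, median 0.43), with a camera adjusted p of 0.166 and adjusted p = 0.947 with an estimated correlation. The ETS factor Etv1 rose by 2.55 ± 0.48, the feedback inhibitor Spry1 by 1.93 ± 0.38 and Phlda1 by 1.49 ± 0.31. Of 14 steroidogenic and granulosa cell genes, 6 fell, 0 rose and 8 did not pass (6 fell adjusted over the list alone, median -0.77), with a camera adjusted p of 0.126 and adjusted p = 0.947 with an estimated correlation, and the inhibin subunit Inha fell by 2.61 ± 0.56.

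Among single genes of large change, the cadherin Cdh6 rose by 9.34 ± 1.43 (log2, SE) and Hmgcll1 by 8.58 ± 1.06. Pcdh10, a protocadherin, had 2 counts in Pten/Nf1, a ratio of 3436 (95% counting interval 951 to 28382). The sphingosine-1-phosphate receptor S1pr5 fell by 8.06 ± 0.74, Tmem114 fell by 8.74 ± 1.15 and Ccdc187 fell by 7.79 ± 1.13. Soga3 had 1 count in Ccne1/Akt2/Kras and a ratio of 1488 in favour of Pten/Nf1 (interval 267 to 58792), and the G-protein-coupled receptor Gpr37 had 2 counts and a ratio of 423 (117 to 3499). The tight junction gene Cldn2 rose by 10.65 ± 1.70 and the transcription factor Hnf1b by 9.34 ± 1.71, but limma-voom gave adjusted p values of 0.17 and 0.0648, the highest over their alternatives (lowest 2.90e-16 and 8.91e-07). In all, edgeR called 3615 of 17431 genes (20.7%), 1689 higher and 1926 lower in Ccne1/Akt2/Kras, and 2400 at a fold of at least 2. Both genotypes did not overlap for 3449 genes (19.8%), against 2.86% by chance. The count was 2319 without tumour 7, and 1810 when only these 8 libraries were fitted, and with DESeq2 more were higher than lower (2738 and 2541).

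Ccne1/Akt2/Kras against Brca1/Myc had the most called genes of the 3 comparisons in the fit of all 12 libraries, but with 4381 calls fewer than Pten/Nf1 against Brca1/Myc (4678) when only the 2 genotypes compared were fitted. Higher in Ccne1/Akt2/Kras were 14 of 21 macrophage and monocyte genes, 18 of 26 myeloid chemokines and cytokines (2 fell), 5 of 8 genes of cytosolic DNA sensing, 14 of 32 interferon-stimulated genes (1 fell), 7 of 20 p53 targets and 12 of 32 cell cycle genes (1 fell). Lower were 8 of 9 mesothelial and 6 of 14 steroidogenic ovary genes (2 rose). Each of these lists was lost with an estimated correlation (adjusted p = 0.385 to 0.975). Pmaip1, a pro-apoptotic p53 target (ENSMUSG00000024521.8, chromosome 18, 66458533 to 66465565), had 31.2 ± 4.99 CPM (SD, n = 4) in Ccne1/Akt2/Kras and 3.43 ± 1.11 in Brca1/Myc. Cgas, the cytosolic DNA sensor (ENSMUSG00000032344.17, chromosome 9, 78430526 to 78443237), had 14.2 ± 5.85 and 1.72 ± 0.844 CPM. Pgc, the precursor of a gastric protease (ENSMUSG00000023987.14, chromosome 17, 47726842 to 47734482), had 0 counts in Ccne1/Akt2/Kras and 70.1 ± 41.3 CPM in Brca1/Myc, at least 2271-fold lower.

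Among 21 macrophage and monocyte genes, 14 rose, 0 fell and 7 did not pass (16 rose adjusted over the list alone, median log2 fold change 1.55), with a camera adjusted p of 2.75e-05 and adjusted p = 0.975 with an estimated correlation. The scavenger receptor Msr1 rose by 1.83 ± 0.36 (SE), the integrin Itgam by 1.89 ± 0.37, the lysozyme gene Lyz2 by 2.09 ± 0.45 and the Fc receptor Fcgr1 by 2.00 ± 0.46. Among 26 myeloid chemokines and cytokines, 18 rose, 2 fell and 6 did not pass (18 and 2 adjusted over the list alone, median 1.84), with a camera adjusted p of 0.000966 and adjusted p = 0.385 with an estimated correlation. Il34, a ligand of the CSF1 receptor, rose by 1.60 ± 0.28, Tslp by 2.04 ± 0.39, Osm by 1.91 ± 0.39 and the neutrophil attractant Cxcl5 by 3.17 ± 0.65.

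Among 8 genes of cGAS-STING and innate DNA sensing, 5 rose, 0 fell and 3 did not pass (7 rose adjusted over the list alone, median log2 fold change 1.03), with a camera adjusted p of 0.0203 and adjusted p = 0.576 with an estimated correlation. Cgas rose by 3.03 ± 0.45 (SE), the inflammasome sensor Aim2 by 1.72 ± 0.41 and Tmem173, which encodes STING, by 0.93 ± 0.24. Among 32 interferon-stimulated genes, 14 rose, 1 fell and 17 did not pass (14 and 1 adjusted over the list alone, median 1.25), with a camera adjusted p of 0.0025 and adjusted p = 0.975 with an estimated correlation. Oasl1 rose by 2.55 ± 0.31, Isg15 by 2.71 ± 0.59 and Irf7 by 2.06 ± 0.46. The interferon list's adjusted p was 0.0668 without tumour 4, in a range of 1.11e-05 to 0.975. Of the 9 lists called by camera here, it was the 1 whose scores overlapped (3.84 to 5.42 in Brca1/Myc, exact permutation p = 0.257).

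Although every genotype is labelled as lacking Tp53, 7 of 20 p53 targets rose, 0 fell and 13 did not pass (7 rose adjusted over the list alone, median log2 fold change 0.50), with a camera adjusted p of 0.0377 and adjusted p = 0.385 with an estimated correlation. Pmaip1 rose by 3.19 ± 0.30 (SE), the cell cycle inhibitor Cdkn1a by 1.55 ± 0.31 and the pore-forming gene Bax by 0.90 ± 0.23. The list's adjusted p was 0.073 without tumour 1 and 0.0626 without tumour 4, in a range of 0.000554 to 0.385. Its score was also higher in every Pten/Nf1 than in every Brca1/Myc tumour (means 4.38 and 4.01, exact permutation p = 0.0286, adjusted 0.133). There 6 members were higher and 0 lower at an unadjusted p under 0.05, and 3 and 0 by DESeq2, but camera did not call the list. The difference was thus not particular to Ccne1/Akt2/Kras. Among 17 immediate early and dissociation stress genes, 8 rose, 0 fell and 9 did not pass (10 rose adjusted over the list alone, median 0.97), with a camera adjusted p of 0.00195 and adjusted p = 0.576 with an estimated correlation. The heat shock genes Hspa1b, Hspa1a and Hsph1 rose by 4.01 ± 0.73, 4.87 ± 0.95 and 2.28 ± 0.46, and the immediate early gene Junb by 2.27 ± 0.43. The stress list's score did not overlap between both genotypes (means 5.56 and 4.32, exact permutation p = 0.0286, adjusted 0.109). Whether the handling of the tumours differed between genotypes was not tested. Among 32 cell cycle genes, 12 rose, 1 fell and 19 did not pass (17 and 1 adjusted over the list alone, median 0.71), with a camera adjusted p of 0.00134 and adjusted p = 0.975 with an estimated correlation. Birc5, which encodes survivin, rose by 1.65 ± 0.33, the replication licensing factor Cdc6 by 1.44 ± 0.35 and Mcm5 by 1.12 ± 0.25, and Rrm1 fell by 0.86 ± 0.18.

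In the mesothelium list, 8 of 9 members fell, 0 rose and 1 did not pass (8 fell and 1 rose adjusted over the list alone, median log2 fold change -4.59), with a camera adjusted p of 9.91e-07 and adjusted p = 0.576 with an estimated correlation. Upk1b fell by 4.20 ± 0.54 (SE), Gpm6a fell by 6.26 ± 0.89, Rspo1 fell by 5.45 ± 0.80 and the transcription factor Bnc1 fell by 5.50 ± 0.87. Of 14 steroidogenic and granulosa cell genes, 6 fell, 2 rose and 6 did not pass (7 fell and 2 rose adjusted over the list alone, median -1.37), with a camera adjusted p of 0.0377 and adjusted p = 0.975 with an estimated correlation. Inha fell by 5.58 ± 0.63, the steroidogenic regulator Nr5a1 fell by 5.80 ± 0.99 and the cholesterol transporter Star fell by 2.67 ± 0.54. Cyp17a1, an enzyme of androgen synthesis, had 2 counts in Ccne1/Akt2/Kras, a ratio of 283 in favour of Brca1/Myc (95% counting interval 78.0 to 2340). The ovary list's adjusted p was 0.0941, 0.0605 and 0.0885 without tumours 1, 2 and 4, in a range of 0.00401 to 0.975 that includes 0.0757 with limma-voom and 0.204 and 0.19 with limma-trend on TPM + 1 and TPM + 0.1.

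The RAS-MAPK output list did not pass (camera adjusted p = 0.278, adjusted p = 0.975 with an estimated correlation), with 9 of 23 members higher, 1 lower and 13 not passed (9 and 2 adjusted over the list alone, median log2 fold change 0.38). Etv1 rose by 3.90 ± 0.51 (SE), cyclin D1 gene Ccnd1 by 2.60 ± 0.47, Phlda1 by 2.20 ± 0.32 and the ephrin receptor Epha2 by 1.36 ± 0.30. In the Müllerian list 3 of 25 rose, 2 fell and 20 did not pass (3 and 2 adjusted over the list alone, camera adjusted p = 0.919, adjusted p = 0.975 with an estimated correlation), with a median of 0.76 and a mean of 0.72 while the test's direction was down. Its member Wt1 fell by 5.24 ± 0.87 and Muc16 fell by 6.94 ± 1.18.

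Among single genes of large change, the homeobox gene Nkx2-3 rose by 9.67 ± 1.59 (log2, SE), the adhesion receptor Adgra1 by 8.26 ± 1.10 and the cadherin Cdh19 by 7.86 ± 1.17. Tmem114 fell by 9.98 ± 1.18, Ccdc187 fell by 9.26 ± 1.18, Hsd17b3, which makes testosterone, fell by 8.57 ± 1.08 and the sodium-activated potassium channel Kcnt1 fell by 7.61 ± 0.71. Soga3 had 1 count in Ccne1/Akt2/Kras and a ratio of 2470 in favour of Brca1/Myc (95% counting interval 443 to 97590), and Gpr37 2 counts and a ratio of 768 (212 to 6348). In all, edgeR called 5729 genes (32.9%), 3062 higher and 2667 lower in Ccne1/Akt2/Kras, and 3823 at a fold of at least 2. Both genotypes did not overlap for 5484 genes (31.5%), against 2.86% by chance. Fewer were higher than lower with limma-voom (2485 and 2951), limma-trend on TPM + 1 (1797 and 3845) and TPM + 0.1 (1811 and 3820), and without tumour 10 (1867 and 1987). The call of each of the 20 genes of largest change was kept in every fit without 1 tumour that tested it, here and against Pten/Nf1, and 1 of them here was tested in only 11 of the 12 fits.

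Pten/Nf1 against Brca1/Myc had the fewest called genes in the fit of all 12 libraries, but the most when only the 2 genotypes compared were fitted (4678, against 4381 and 1810). Higher in Pten/Nf1 were 8 of 11 B and plasma cell genes, 7 of 21 macrophage and monocyte genes, 4 of 15 neutrophil genes and 3 of 20 fibroblast and stroma genes. Of 11 genes of secretory and intestinal-type epithelium, 2 were lower, and that list was also lost with limma-voom, limma-trend, the CPM filter and without tumour 8. Each of these lists was lost with an estimated correlation (adjusted p = 0.238 to 0.769). Ighm, the immunoglobulin heavy chain of IgM (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730), had 914 ± 701 CPM (SD, n = 4) in Pten/Nf1 and 47.0 ± 20.7 in Brca1/Myc. Ncan, a proteoglycan of neural matrix, had 1855 counts in Pten/Nf1 and 1 count in Brca1/Myc, a ratio of 1966 (95% counting interval 352 to 77694).

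Among 11 B and plasma cell genes, 8 rose, 0 fell and 3 did not pass (9 rose adjusted over the list alone, median log2 fold change 2.52), with a camera adjusted p of 4.20e-07 and adjusted p = 0.394 with an estimated correlation. Ighm rose by 4.28 ± 0.68 (SE), and the plasma cell gene Mzb1 by 5.86 ± 1.13, with an adjusted p of 0.0551 without tumour 10. The mean log2 CPM of this list was 1.85 in Pten/Nf1 tumour 8, 3.85 to 4.52 in tumours 5 to 7, and 0.38 to 0.99 in Brca1/Myc. Among 21 macrophage and monocyte genes, 7 rose, 0 fell and 14 did not pass (17 rose adjusted over the list alone, median 1.37), with a camera adjusted p of 1.65e-09 and adjusted p = 0.478 with an estimated correlation. The monocyte antigen Ly6c2 rose by 3.45 ± 0.62. The lysosomal gene Cd68 rose by 1.41 ± 0.32, with adjusted p values of 0.0744, 0.0777 and 0.0629 without tumours 9, 10 and 5. Among 15 neutrophil genes, 4 rose, 0 fell and 11 did not pass (9 rose adjusted over the list alone, median 1.47), with a camera adjusted p of 0.000167 and adjusted p = 0.238 with an estimated correlation. G0s2 rose by 2.97 ± 0.60, with adjusted p values of 0.0619 and 0.0622 without tumours 9 and 10. Among 26 myeloid chemokines and cytokines, 6 rose, 0 fell and 20 did not pass (8 rose adjusted over the list alone, median 1.25), with a camera adjusted p of 0.000219 and adjusted p = 0.352 with an estimated correlation. The cytokine Lif rose by 1.56 ± 0.35, with adjusted p values of 0.0724, 0.0751, 0.0534 and 0.0527 without tumours 9, 10, 11 and 6.

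Among 20 fibroblast and stroma genes, 3 rose, 0 fell and 17 did not pass (6 rose adjusted over the list alone, median log2 fold change 1.17), with a camera adjusted p of 0.000118 and adjusted p = 0.646 with an estimated correlation. The matrix gene Fbln1 rose by 3.46 ± 0.43 (SE) and the collagen gene Col1a2 by 3.31 ± 0.50. The mean log2 CPM of the fibroblast list was 9.0 in Pten/Nf1 tumour 8 and 7.39 to 8.07 in tumours 5 to 7. Of 17 mesenchymal genes, 3 rose, 0 fell and 14 did not pass (4 rose adjusted over the list alone, median 0.74), with a camera adjusted p of 0.00608 and adjusted p = 0.646 with an estimated correlation. Of 12 mast cell and eosinophil genes, 1 rose, 0 fell and 11 did not pass (1 adjusted over the list alone, median 1.21), with a camera adjusted p of 0.00714 and adjusted p = 0.646 with an estimated correlation. Of 19 hypoxia and glycolysis genes, 2 rose, 0 fell and 17 did not pass (2 adjusted over the list alone, median 0.56), with a camera adjusted p of 0.00472 and adjusted p = 0.769 with an estimated correlation, among them Bnip3, which rose by 1.10 ± 0.19. Of 19 immune checkpoint genes, 2 rose, 0 fell and 17 did not pass (3 adjusted over the list alone, median 0.67), with a camera adjusted p of 0.0166 and adjusted p = 0.679 with an estimated correlation. Its adjusted p was 0.076 without tumour 9 and 0.0664 without tumour 5, in a range of 0.00232 to 0.679. The scores of both genotypes overlapped for 5 of the 12 lists called by camera here, which were the fibroblast, hypoxia, checkpoint, mast cell and Müllerian lists.

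Of 11 genes of secretory and intestinal-type epithelium, 2 fell, 0 rose and 9 did not pass (4 fell adjusted over the list alone, median log2 fold change -2.14), with a camera adjusted p of 0.0338 and adjusted p = 0.769 with an estimated correlation. The gastric mucin gene Muc5ac fell by 6.08 ± 1.09 (SE). The secretory list's adjusted p was 0.0593 without tumour 8, 0.152 with the CPM filter, 0.071 with limma-voom, and 0.308 and 0.155 with limma-trend on TPM + 1 and TPM + 0.1, in a range of 0.00421 to 0.769. In the Müllerian list 25 of 25 members did not pass edgeR's test, adjusted over the list alone as well, while 6 were lower at an unadjusted p under 0.05 and 6 by DESeq2 (median -1.01, camera adjusted p = 0.00463, adjusted p = 0.785 with an estimated correlation). Its adjusted p was 0.195 and 0.133 with limma-trend on TPM + 1 and TPM + 0.1, in a range of 0.000238 to 0.785. Of 16 FOXO targets, which AKT signalling represses, 1 fell, 0 rose and 15 did not pass (2 fell adjusted over the list alone, median -0.41), with a camera adjusted p of 0.0368 and adjusted p = 0.646 with an estimated correlation. The FOXO list's adjusted p was 0.0586 without tumour 10 and 0.0739 without tumour 8, in a range of 0.0113 to 0.646.

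Among single genes of large change, the potassium channel subunit Kcns3 rose by 5.32 ± 0.76 (log2, SE), Kctd15 by 5.26 ± 0.78, the fibrillar collagen Col27a1 by 4.60 ± 0.66 and Nsg1 by 4.64 ± 0.77. Pgc fell by 4.76 ± 0.60, Kcnt1 fell by 4.48 ± 0.60, Hsd17b3 fell by 4.38 ± 0.84 and the imprinted gene Peg3 fell by 3.51 ± 0.70. Of the 20 genes of largest change, 10 kept their call in all 12 fits that left out 1 tumour, and Onecut2, Tspyl5, Crabp2, Jchain, Grb7, Rragd, Mcf2, Marveld2, Slc44a3 and Sectm1b did not. In all, edgeR called 1748 genes (10.03%), 985 higher and 763 lower in Pten/Nf1, and 1023 at a fold of at least 2. Both genotypes did not overlap for 5322 genes (30.5%), against 2.86% by chance. The count was 370, 354, 936, 620, 703 and 920 without tumours 9, 10, 11, 5, 6 and 8, and 3889 without Ccne1/Akt2/Kras tumour 1, whose spread enters the shared dispersion. It was 3545 with DESeq2, 4678 when only these 8 libraries were fitted, and 3074 with limma-trend on TPM + 1, where 645 were higher and 2429 lower (619 and 2173 on TPM + 0.1).

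Camera with an estimated correlation called 0 of 42 lists in each comparison, where 1, 3 and 3 lists had an unadjusted p under 0.05 in Ccne1/Akt2/Kras against Pten/Nf1, Ccne1/Akt2/Kras against Brca1/Myc and Pten/Nf1 against Brca1/Myc. Camera with a preset correlation called 8, 9 and 12 lists and fry 7, 8 and 6. An exact permutation test of the mean log2 CPM of each list, 4 tumours against 4 and two-sided, cannot go below a p of 0.0286. This exact test gave that p for 5, 11 and 9 lists, and 0 passed adjustment over 42 lists (lowest adjusted p = 0.2, 0.109 and 0.133). The mesothelium, DNA sensing and homologous recombination lists reached that p in both comparisons of Ccne1/Akt2/Kras. The macrophage, myeloid chemokine, mesenchymal, p53 target and FOXO target lists reached that p in both comparisons of Brca1/Myc.

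**Figure D3:**
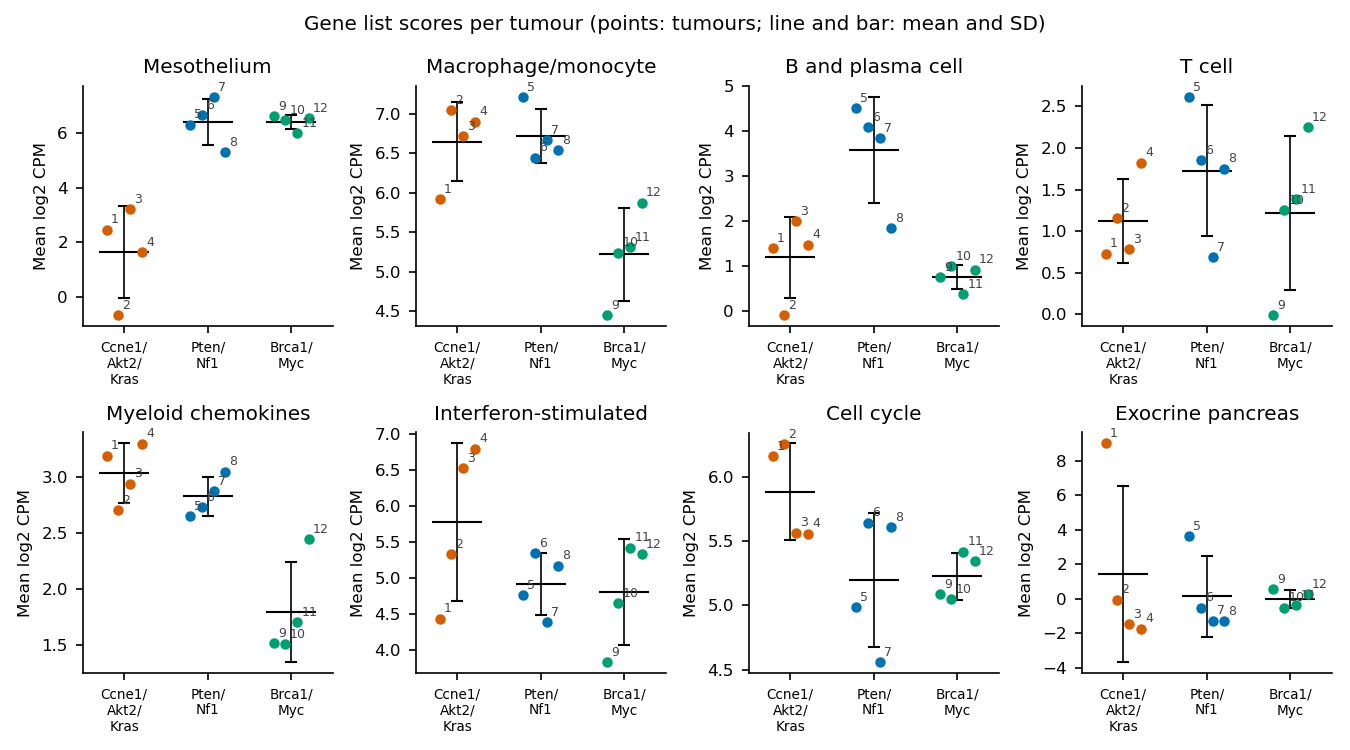
Mean log2 CPM of 8 gene lists in each tumour, by genotype; points are tumours with their numbers, and lines and bars are the mean and SD of 4. Mesothelium scores ran from -0.67 to 3.22 in Ccne1/Akt2/Kras and from 5.31 to 7.32 in the other tumours, and the exocrine pancreas score was 9.02 in tumour 1.

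Each genotype had genes that set it apart from both others, most of them in Ccne1/Akt2/Kras. In that genotype 1094 genes were higher than in both others and 1282 lower, where independent overlap of the calls would give 297 and 295. Both comparisons of a genotype share its 4 tumours, so their calls are not independent, and values by independent overlap are no test of these counts. Higher genes included Brinp3, Cdh6, Cdh19, Adgra1 and Nkx2-3, and lower genes Soga3, Gpr37, Tmem114 and Ccdc187. In Pten/Nf1, 288 were higher and 158 lower (109 and 73.9 by independent overlap); Ncan, at 1855 counts against 1 in each other genotype, was among the higher, as were Col27a1, at 110 ± 67.1 CPM (SD, n = 4), and the Nodal antagonist Lefty1, at 10.2 ± 1.94. In Brca1/Myc, 443 were higher and 557 lower (117 and 173). The higher included Kcnt1, at 91.6 ± 64.5 CPM, Peg3, at 413 ± 256, and the RNA-binding protein gene Igf2bp1, at 31.5 ± 13.8. The lower included Lgi2, at 1.49 ± 0.599 CPM against 49.7 ± 29.0 and 33.0 ± 22.9, and Jrk (ENSMUSG00000046380.3, chromosome 15, 74702301 to 74709535), above which the others rose by 5.05 ± 0.42 and 4.41 ± 0.41 (log2, SE). In 10 simulations without any effect, 0 genes were apart in each set. These simulations held no difference between genotypes, so they do not show the overlap that shared tumours give when genes differ.

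Single libraries moved 5 of these 6 sets by more than 1.5 times, while the genes lower in Ccne1/Akt2/Kras numbered 962 to 1730. The genes higher in Ccne1/Akt2/Kras numbered 679 without tumour 7. Those higher in Pten/Nf1 numbered 682 without tumour 1, and 124, 113, 185, 90, 85, 147 and 183 without tumours 5, 6, 7, 9, 10, 11 and 12. Those lower in Pten/Nf1 numbered 424 without tumour 1, and 57, 62, 85, 83, 41, 45, 83 and 96 without tumours 5, 6, 7, 8, 9, 10, 11 and 12. Those higher in Brca1/Myc numbered 918 without tumour 1, and 135, 174, 209, 83, 88 and 280 without tumours 5, 6, 8, 9, 10 and 11. Those lower in Brca1/Myc numbered 1020 without tumour 1, and 236, 280, 292, 130, 107 and 296 without the same others.

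The median expression of the genes of a chromosome also differed between genotypes. Over 9454 genes, the median expression of all genes on chromosome 3 was higher in Ccne1/Akt2/Kras, by 0.45 (log2) over Pten/Nf1 and 0.62 over Brca1/Myc, and that of chromosome 6 differed by -0.46 and -0.45. Against Pten/Nf1, chromosome 8 was higher by 0.37, and chromosomes 16, 18 and 19 differed by -0.38, -0.31 and -0.33. Against Brca1/Myc, chromosome 4 was higher by 0.33, and chromosomes 2 and 13 differed by -0.37 and -0.37. Between Pten/Nf1 and Brca1/Myc, chromosome 15, which carries Myc, differed by 0.34. All 4 tumours of the genotype lay beyond all 8 others for 5 of 20 chromosomes in Ccne1/Akt2/Kras (3 and 4 higher, 6, 13 and 16 lower), 3 in Pten/Nf1 (1 and 19 higher, 8 lower) and 3 in Brca1/Myc (2 and 13 higher, 4 lower), where chance gives 0.0808 per genotype. Each of these had an exact permutation p of 0.00404 (two-sided, 4 tumours against 8), adjusted to 0.022 over 60 tests. Kras lies on chromosome 6, but a link between its counts and the shift of that chromosome was not tested. Tumour 1 had more Kras counts than tumours 2 to 4. Its chromosome 6 value was -0.28, against -0.44, -0.23 and -0.27 in those tumours.

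**Figure D4:**
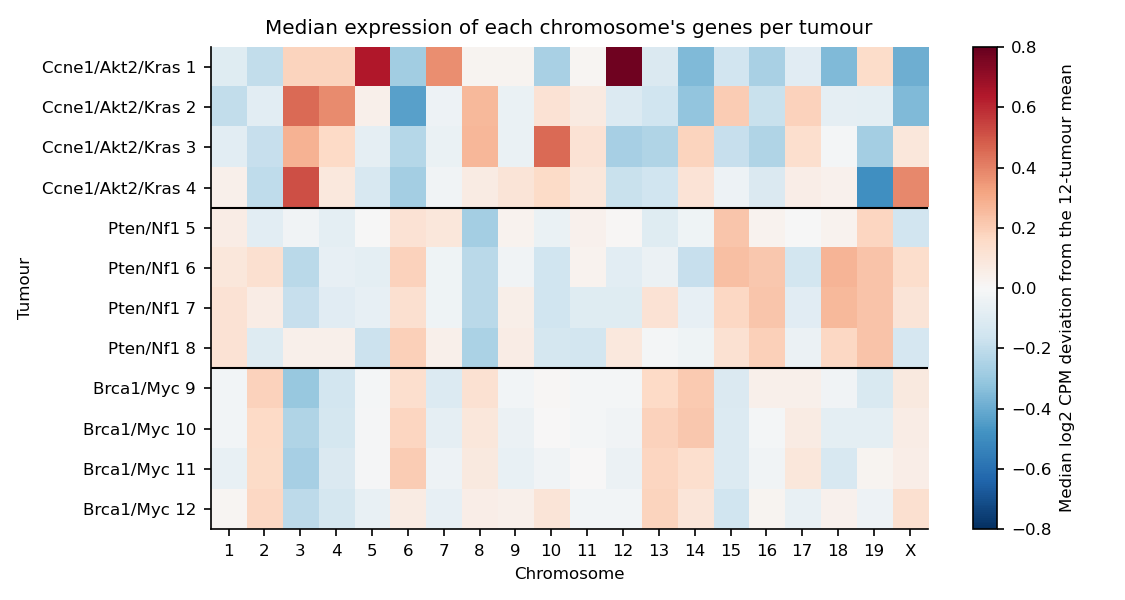
Median deviation of log2 CPM from the mean of the 12 tumours for the genes of each chromosome (columns) in each tumour (rows), with red above and blue below 0. Chromosome 3 was higher in all 4 Ccne1/Akt2/Kras tumours than in all 8 others, and chromosome 12 was raised by 0.78 in tumour 1.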

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

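Of the tests in this part, those of host tissue in single libraries, of less peritoneal tissue, of a lower tumour-cell share and of lymphoid tissue were chosen after the result was seen.

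The median expression of chromosomes shifted between genotypes, with 12 contrasts of a chromosome beyond 0.3 (log2) and beyond all of 1000 relabellings of its genes. A median does not show whether a shift runs along all of a chromosome. A bias from GC content or gene length would have removed these shifts, yet 10 of the 12 stayed beyond 0.3 after regression on both, the exceptions being chromosome 4 against Brca1/Myc (from 0.34 to 0.30) and chromosome 18 against Pten/Nf1, which was at -0.30 both before and after regression. Host tissue in single libraries would shift a chromosome in some tumours of a genotype only. Yet in 11 of the 12 contrasts the 4 tumours of one genotype lay beyond the 4 of the other (adjusted exact permutation p = 0.0312). These 12 were chosen out of 60 by the difference between genotypes in the same libraries. The adjustment covers the 12 alone, so this p is no independent support. Chromosome 3 was higher in all 4 Ccne1/Akt2/Kras tumours than in the 8 others (exact permutation p = 0.00404, adjusted to 0.022 over 60 tests). For chromosome 18 (-0.35, -0.07, -0.01 and 0.04 in tumours 1 to 4, lowest Pten/Nf1 value 0.03, exact permutation p = 0.0571) host tissue in single libraries stays open. A candidate explanation is that chromosomes were gained or lost and that the tumours of a genotype share the change. Whether the injected organoids already carried it was not tested, since no organoid or DNA data are at hand.

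In the mesothelium list, which is lost with an estimated correlation (adjusted p = 0.947 and 0.576), 8 of 9 genes were lower in Ccne1/Akt2/Kras than in each other genotype, at 10.3 ± 9.89 CPM of Upk3b (SD, n = 4) against 719 ± 477 in Pten/Nf1 and 486 ± 103 in Brca1/Myc, and none of the 9 members of the list is in another list. The members that fell lie on 6 chromosomes, which argues against the loss of a single segment. Less carried-over peritoneal fat with its lining would lower adipocyte genes by a similar amount, and the mesothelium score differed by -4.74 and the adipocyte score by -0.77 from the 8 others (exact permutation p of the difference between scores 0.0202), which argues against it as the whole cause. A part stays open, since 12 of 12 adipocyte genes had a log2 fold change below 0 against Pten/Nf1 (median -1.55, 5 of 12 against Brca1/Myc), the adipocyte score's SD was 2.24, 2.43 and 1.46 within the 3 genotypes, and Lpl had 74.0 ± 12.4 CPM against 417 ± 189 and 543 ± 69.7. The adipocyte comparison does not cover other host tissue such as ovary. The mean steroidogenic and granulosa cell score was also lower, at 0.86 ± 0.61 against 2.02 ± 0.51 in Pten/Nf1 and 2.54 ± 0.48 in Brca1/Myc. Its exact permutation p was 0.0571 and 0.0286 (adjusted 0.2 and 0.109), so less ovary tissue stays open too. A genotype difference may underlie the pattern, either in the mesothelial cells present or in genes the tumour cells themselves express, and both stay open as untested.

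Of 21 macrophage genes, 14 were lower in Brca1/Myc than in Ccne1/Akt2/Kras and 7 than in Pten/Nf1 (Lyz2 at 379 ± 130 CPM, SD, n = 4, against 1618 ± 806 and 1433 ± 502) and 6 and 8 of 11 B and plasma cell genes were higher in Pten/Nf1 than in Ccne1/Akt2/Kras and Brca1/Myc, lists that are lost with an estimated correlation (adjusted p = 0.975, 0.478, 0.947 and 0.394). A larger share of tumour cells in Brca1/Myc would lower all host types alike, and the macrophage score differed by -1.47 but the endothelium score by 0.03 from the 8 others (exact permutation p of the difference between scores 0.00808), which argues against it as the whole cause. The mesenchymal list moved with the macrophages, since its score was 5.94 ± 0.41 in Brca1/Myc, below every tumour of both others (6.55 ± 0.43 and 6.76 ± 0.26, exact permutation p 0.0286 for each, adjusted 0.109 and 0.133). The fibroblast score was 7.06 ± 0.54 against 7.46 ± 0.19 and 8.13 ± 0.66, but tumours overlapped in both comparisons (exact permutation p 0.2 and 0.0857). Carried-over lymphoid tissue would bring T cells, and the B and plasma cell score rose by 2.60 and the T cell score by 0.56 (exact permutation p 0.0162), which argues against it as the whole cause, although 15 of 18 T cell genes were below 0 in Ccne1/Akt2/Kras against Pten/Nf1 (median -0.88) and 16 of 18 above 0 in Pten/Nf1 against Brca1/Myc (median 0.41). A difference in the immune cells that genotypes draw may add to the pattern and remains untested.

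Other splits of the same libraries tested whether chance can be excluded. For the genes called in Ccne1/Akt2/Kras against Pten/Nf1, against Brca1/Myc and in Pten/Nf1 against Brca1/Myc, 1 of 35 splits, the real one, gave a count as large as 3615, 5729 and 1748 (highest other 309, 1 and 0). For lists called by camera, 33, 33 and 31 of 35 splits gave as many as the real 8, 9 and 12 (highest other 23, 25 and 25), so chance cannot be excluded for the number of lists. The other splits gave a median of 13, 15.5 and 18 lists, above the real counts. Camera's adjusted p values at the preset correlation, given above list by list, thus do not show that a list differs beyond chance. For genes differing among the 3 genotypes, 1 of 100 splits gave as many as 6518 (highest other 96). For genes apart, 1 of 100 splits gave as many as the 1094, 288 and 443 higher (highest other 1 for each) and the 1282, 158 and 557 lower (highest other 4 for each) in Ccne1/Akt2/Kras, Pten/Nf1 and Brca1/Myc. Chance is thus unlikely to give the gene counts, at shares of 1 of 35 and 1 of 100, the smallest possible here. Mixed splits carry genotype differences in their spread, which lowers their counts of genes. Nor do the splits separate genotype from anything else that its tumours share.

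In 521 groups of 4 values, 40 had a tumour whose gap to the next, as a share of the group's range, exceeded Dixon's 95% critical value, where chance sets apart about 1 in 20 groups (26.05 here). The genes tested were those named in the text, among them host tissue and Hoxb genes chosen after their values were seen. Related genes and scores are also not independent, so 40 against 26.05 is no test. Below, the number in brackets is the gap as a share of the group's range. Ccne1/Akt2/Kras tumour 1 was highest in its group for the exocrine pancreas score (0.844), Ctrb1 (0.855), Pnlip (0.846), the keratin and squamous score (0.884), chromosome 12 (0.852) and chromosome 7 (0.943). Tumour 1 was lowest for Cgas (0.955, at 5.42 CPM), Fcgr1 (0.9), Il34 (0.874), Pten (0.869, at 51.7 CPM), Tspyl5 (0.86) and the share of mitochondrial counts (0.947). Tumour 2 was highest for the mesenchymal score (0.922) and chromosome 2 (0.8291, just above the critical value), and lowest for Hoxb3 (0.914) and Cldn2 (0.845, at 0.357 CPM). Tumour 3 was lowest for Jrk (0.87), and tumour 4 was highest for the regulatory T cell score (0.851).

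Pten/Nf1 tumour 8 was lowest for Jchain (0.989, at 45.1 CPM), Igkc (0.889), Mzb1 (0.932, at 0.208 CPM) and the oocyte score (0.897), and highest for the skeletal muscle score (0.934), Acta1 (0.839), Ckm (0.936) and Myh4 (0.909). Pten/Nf1 tumour 5 was highest for the exocrine pancreas score (0.841) and lowest for chromosome 19 (0.904). Tumour 6 was lowest for G0s2 (0.932, at 4.82 CPM). Tumour 7 was lowest for Birc5 (0.995, at 18.5 CPM) and Col1a2 (0.888), and highest for Peg3 (0.929). Brca1/Myc tumour 9 was highest for the oocyte score (0.902) and Pdk1 (0.849), and lowest for Pmaip1 (0.909) and the share of histone counts (0.874). Tumour 11 was highest for chromosome 11 (0.852), and tumour 12 was highest for Hoxb5 (0.904) and Hoxb7 (0.876) and lowest for chromosome 15 (0.89).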

How the results depend on the processing

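The authors' size factors, leaving out tumours 1 and 8 together, and exact permutation of list scores were chosen after seeing the data. No paired analysis was possible because each tumour has its own number and no label links a tumour of one genotype to a tumour of another. Over the alternatives, 0 values reversed among genes called in the main fit or the alternative, and among lists called in the main fit. Of the values of single genes, 6134 kept their side of the threshold, 445 fell below it and 132 passed it. For genes called in neither fit, a change of direction was not counted. Of the values of lists, 616 kept direction and side of the threshold and 80 fell below it. Genotype separation kept its sign under all its alternatives. At the depth and spread of these libraries, 11 to 20% of simulated changes by a fold of 2 and 75 to 77% by a fold of 4 were recovered. The simulated data gave 90 to 101 calls per comparison, against 1748 to 5729 in the real ones. Adjustment is stricter where fewer genes change, so these rates do not carry over to the real comparisons. How far depth alone limits recovery was not tested.

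Leaving out each tumour in turn, genes called numbered 2319 to 5141 for Ccne1/Akt2/Kras against Pten/Nf1, 3854 to 6777 against Brca1/Myc, 354 to 3889 for Pten/Nf1 against Brca1/Myc and 4500 to 8689 among the 3 genotypes. Genes higher and lower apart numbered 679 to 1516 and 962 to 1730 in Ccne1/Akt2/Kras, 85 to 682 and 41 to 424 in Pten/Nf1, and 83 to 918 and 107 to 1020 in Brca1/Myc. Lists called numbered 7 to 10, 7 to 10 and 11 to 17, and the separation ran from 43.0 to 52.0. Of the called genes named, 68 of 87, 88 of 93 and 27 of 72 kept their call in every fit that tested them, which was 12 fits for all but 1 gene (11 fits, among the 88).

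With no filter on low counts, Pten/Nf1 against Brca1/Myc gave 1031 genes, genes lower in Pten/Nf1 were 57, those higher and lower in Brca1/Myc were 235 and 346, and 13 lists were called for Ccne1/Akt2/Kras against Pten/Nf1. With limma-trend on TPM + 1 the same counts of genes were 3074, 425, 1475 and 266, and on TPM + 0.1 they were 2792, 433, 1247 and 296. These fits change test, scaling and offset at once, and moved the median log2 fold change of all genes by -0.22 and -0.23 (TPM + 1 and TPM + 0.1) for Ccne1/Akt2/Kras against Brca1/Myc and by -0.26 and -0.27 for Pten/Nf1 against Brca1/Myc, and the share of called genes that were higher fell from 53.4% to 31.9 and 32.2% and from 56.4% to 20.98 and 22.2%. With DESeq2, Pten/Nf1 against Brca1/Myc gave 3545, genes higher in Ccne1/Akt2/Kras were 1754, those higher and lower in Pten/Nf1 were 565 and 377, and in Brca1/Myc 920 and 1038. DESeq2 shared 98.7, 98.7 and 99.8% of the edgeR calls. Fitting only the 2 genotypes compared gave 1810 and 4678 for both comparisons of Pten/Nf1. An absolute log2 fold change of at least 1 gave 2400 and 1023, and apart 697 higher in Ccne1/Akt2/Kras, 184 higher and 40 lower in Pten/Nf1, and 225 and 358 in Brca1/Myc, since fewer genes can pass. Without tumours 1 and 8, Pten/Nf1 against Brca1/Myc gave 2839, with 610 higher and 336 lower in Pten/Nf1. Camera with an estimated correlation and exact permutation of list scores each gave 0, 0 and 0 lists, and fry gave 6 for Pten/Nf1 against Brca1/Myc. The causes of these changes were otherwise not tested.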

Other observations

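The tests of the Hox clusters and of runs of neighbouring genes in this part were chosen after the result was seen. The Hoxb cluster, homeobox genes that set position along the body axis, was higher in Ccne1/Akt2/Kras than in both other genotypes as a block. All 8 tested genes, Hoxb2 to Hoxb9 (chromosome 11, 96271457 to 96354012), rose against both others and kept both calls in all 12 fits that left out 1 tumour, with a median log2 fold change of 5.46 over Pten/Nf1 and 4.82 over Brca1/Myc. The labels do not say whether the 4 tumours grew from separate organoid clones, so the block is not shown to be an effect of the genotype. Hoxb6 had 72.5 ± 49.9 CPM (SD, n = 4) in Ccne1/Akt2/Kras, 0.749 ± 0.305 in Pten/Nf1 and 1.76 ± 0.641 in Brca1/Myc, and Hoxb2 had 28.8 ± 12.2, 0.712 ± 0.421 and 0.858 ± 0.0793. Of the other clusters, 2 of 9 Hoxa genes were higher and 1 lower, 0 of 8 Hoxc genes were higher and 2 lower (Hoxc13 fell by 6.16 and Hoxc6 fell by 3.13 against Pten/Nf1), and 3 of 5 Hoxd genes were higher.

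Among 12946 genes in order along the genome, the densest run of 10 neighbours held 8 genes higher in Ccne1/Akt2/Kras, which were the Hoxb genes, where the highest of 1000 shuffles held 7. With calls shuffled within each chromosome, 161 of 1000 held 8 or more somewhere in the genome, and the highest on chromosome 11 was 6. A second run on chromosome 6 (30747554 to 34396950) held 8 genes lower in Ccne1/Akt2/Kras, namely Copg2, Mkln1, Podxl, Plxna4, Chchd3, Akr1b3, Akr1b8 and Akr1b10, where the highest of 1000 shuffles also held 7. The median expression of chromosome 6 was lower in Ccne1/Akt2/Kras, and 20.9% of its genes were lower there, against 6.67% elsewhere. How this shift runs along the chromosome was not tested. With calls shuffled within each chromosome, 32 of 1000 held 8 or more on chromosome 6 (highest 9). The run is thus not shown to be more than part of that shift. In the other genotypes the densest runs held 4 higher and 4 lower genes in Pten/Nf1 (highest of the shuffles 4 and 5) and 4 and 5 in Brca1/Myc (6 and 6).

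Genes of other host tissues were high in some tumours of each genotype. The pancreatic digestive enzyme genes Ctrb1, Cpa1 and Pnlip had 1660, 706 and 612 CPM in Ccne1/Akt2/Kras tumour 1, and the exocrine pancreas score was 9.02 there, 3.64 in Pten/Nf1 tumour 5 and at most 0.54 in the other tumours. Skeletal muscle genes were highest in Ccne1/Akt2/Kras tumour 4, at 1209 CPM of the actin gene Acta1, 1297 CPM of the myosin gene Myh4 and 466 CPM of the creatine kinase gene Ckm. The skeletal muscle score was 8.55 in that tumour, 6.26 in Brca1/Myc tumour 10, 5.04 in Pten/Nf1 tumour 8, 4.90 in Ccne1/Akt2/Kras tumour 2 and 4.36 in Brca1/Myc tumour 11.

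T cell genes showed no called difference. In edgeR 0 of 18 T cell genes passed in each comparison, where 1 was higher and 1 lower, 1 higher and 0 lower, and 0 and 0 at an unadjusted p under 0.05, and DESeq2 called 0 in each. For cytotoxic effector genes, edgeR called 0 of 13 in Ccne1/Akt2/Kras against Pten/Nf1, where 1 was higher and 1 lower at an unadjusted p under 0.05 and DESeq2 called 0, and against Brca1/Myc it called 2 higher and 1 lower (0 and 0 when adjusted over the list alone). The list of FOXO targets did not pass for Ccne1/Akt2/Kras against Brca1/Myc, with 4 of 16 members lower, 1 higher and 11 not passed, 4 and 1 adjusted over the list alone, at a camera adjusted p of 0.0857, and adjusted p = 0.975 with an estimated correlation.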
